A study of Homo sapiens with 7 samples.

How the data were processed

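H3K4me3, the trimethylated form of histone H3 lysine 4 that marks active promoters, was mapped by chromatin immunoprecipitation and sequencing in primary human pulmonary arterial endothelial cells. The labels give 7 samples: 3 immunoprecipitated libraries from normoxia, 3 from hypoxia at 0.2% oxygen for 24 hours, and 1 control. The control was not analysed here. Cells were grown in an endothelial medium and DNA was sequenced on a DNBSeq instrument with 20M reads planned, per the labels. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates were separate cultures or donors. The p-values of comparisons between groups of libraries therefore measure only the spread between these libraries, which may be technical. The tests of chromosomes and of neighbouring regions count regions, so their p-values hold no spread between libraries.

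Reads were aligned to hg19 with STAR 2.7.9a and peaks were called with MACS2 2.2.7.1, per the submitters' processing notes. The command lines, the read filters and the use of the control in peak calling are not given in the sources used here. Each deposited file holds the peaks of 1 library, so peaks were called per library and not on pooled libraries. The deposited lists give each peak an interval, a summit, a fold enrichment (a ratio to the local background within the library), a −log10 p and a −log10 q. The deposited score is the whole part of 10 times the −log10 q in 99.93% of the peaks used. The smallest −log10 q in a list lay between 1.32 and 1.46, so a threshold of 0.05 on q fits the values of every list. Scores, folds and −log10 values are the authors' own and were used only to describe, rank or filter peaks within a list. Read counts are not part of these lists, so the depth of each library is unknown and no interval for counting error is given. A deeper library or a stronger immunoprecipitation lengthens a peak list and widens its peaks, and that cannot be separated from a change in the mark by the lists alone.

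Peaks on chromosomes 1 to 22 and X were used. Identical intervals with several summits were counted once, with the values of the summit listed first. Thresholds on −log10 q and the ranking of peaks by −log10 p for equal list length used those values. Peaks on Y, on mitochondrial, patch, haplotype and unplaced contigs, and in 1 short interval of X were left out, the last so that nothing about a donor's sex can be read. Overlapping or touching intervals of the 6 lists were merged into consensus regions with bedtools 2.31.1. A library counted as called in a region with at least 1 base of a peak. A region was called only in hypoxia when all 3 hypoxia libraries and 0 of the 3 normoxia libraries had a call, and the reverse for normoxia. These counts were set beside those of the other 9 ways to split the 6 libraries into 3 and 3. Breadth was the number of bases a library's peaks covered in a region. It was tested in regions called in all 6 libraries with limma 3.58.1 in R 4.3.3, on log2 covered bases centred on each library's median, with eBayes and a trend, two-sided, and Benjamini-Hochberg adjustment at 0.05. Peak number, covered length and median width were compared with a two-sided exact permutation test in scipy 1.17.1, for which 3 against 3 libraries allow no p under 0.1. Chromosomes were compared with Fisher's exact test.

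The breadth test was tested on simulated data built from the 16724 regions, their means and their spread, with 200 regions changed. The simulated noise was normal and independent between regions and libraries. It lacked patterns that many regions of a real library share, so recovery and false calls may differ in the real data. At a log2 change of 0.5 it recovered 20% of 50 regions, at 1 it recovered 58%, at 1.5 it recovered 78% and at 2 it recovered 96%, with 7 false calls. The Benjamini-Hochberg adjustment is less strict when many regions change. These shares therefore hold for 200 changed regions and overstate recovery where few regions change.

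No annotation of hg19 was used here, so regions are named by their hg19 coordinates, counted from 1, and not by genes. The planned promoter counts and the tests of 22 gene lists were therefore not run. Named regions followed a rule set before the data were examined. For group-only regions it took the 5 per direction whose smallest covered length over the libraries with a call was largest. For breadth, where fewer than 3 regions passed in a direction, it took the 5 with the smallest p. Alternatives changed the list length, the threshold, the merging distance, the overlap, the chromosomes, the centring, a minimum breadth, the variance trend and the replicate block, and left out each library in turn. Leaving out both libraries with the lowest median −log10 q, cyclic loess and a subtraction of the smallest peak width were added after the data were seen.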

Results

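The data were 6 lists of H3K4me3 peaks from primary human pulmonary arterial endothelial cells, the cells that line the arteries of the lung. The series asks how this promoter mark differs between normoxia and 24 hours of hypoxia at 0.2% oxygen, with 3 libraries per group. The normoxia lists held 21887, 26478 and 27887 peaks in replicates 1 to 3. The hypoxia lists held 30756, 29858 and 31930 peaks. The depth behind them is unknown.

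Hypoxia libraries had more called peaks. Their mean was 30848 ± 1039 peaks (SD, n = 3) against 25417 ± 3137 (SD, n = 3) in normoxia, a ratio of 1.21, and every hypoxia list was longer than every normoxia list. The two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. At a −log10 q of at least 10 the groups overlapped, with 19769 peaks in hypoxia replicate 2 and 21860 in normoxia replicate 3 (exact permutation test, p = 0.3). Peaks covered 17.1 ± 2.24 Mb (SD, n = 3) in hypoxia and 15.2 ± 3.83 Mb (SD, n = 3) in normoxia, which did not differ by more than the spread (exact permutation test, p = 0.7). Without normoxia replicate 1 the difference in covered length turned, to -0.167 Mb. The median peak width was 445 ± 54.98 bases in hypoxia and 501 ± 88.0 bases in normoxia (SD, n = 3 each; exact permutation test, p = 0.5). The strength of the lists varied within groups. The median −log10 q, as the authors' caller gave it, was 16.5 in normoxia replicate 1 and 16.5 in hypoxia replicate 2, and lay between 31.1 and 43.8 in the other 4 libraries.

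**Figure D1:**
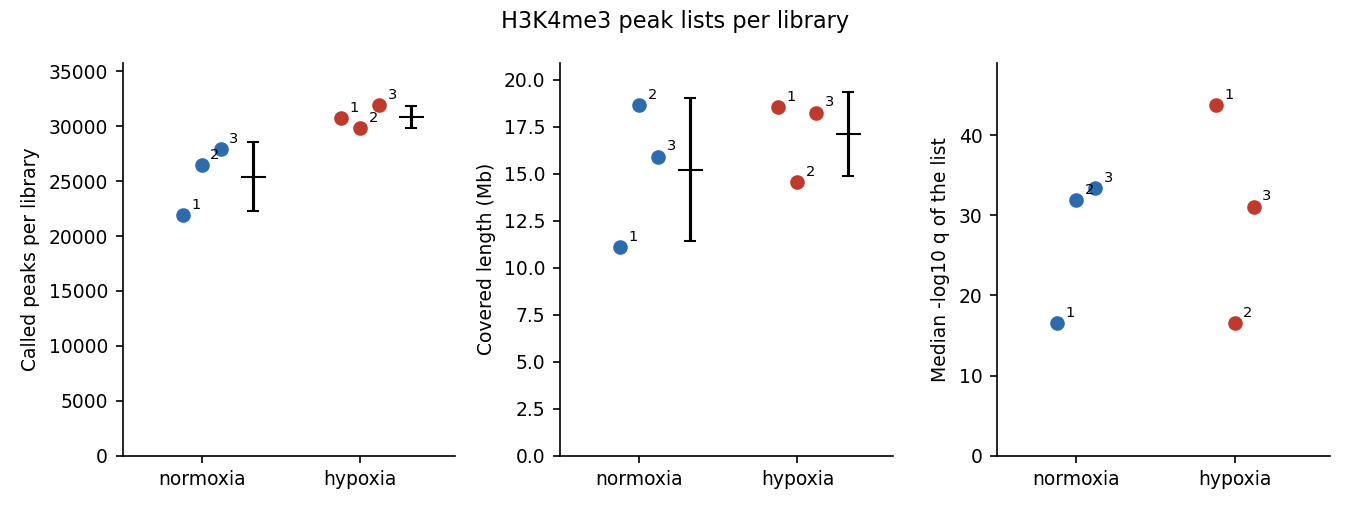
Called peaks, covered length in Mb and median −log10 q of each list, one point per library with its replicate number; black bars in the first 2 panels give the mean and SD of 3 libraries. All 3 hypoxia lists are longer than the longest normoxia list of 27887 peaks, while covered lengths overlap.

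The lists shared much of their H3K4me3 landscape. Merging gave 33424 consensus regions, of which 16724 (50.04%) were called in all 6 libraries and 6573 in 1 library. Shared regions had a median length of 973 bases. The broadest of them by mean covered length lay at chromosome 6, 58776237 to 58779639, with 3342 ± 51.8 covered bases in normoxia and 3244 ± 106 in hypoxia (SD, n = 3 each). It lies close to a centromere, where repeats can give peaks by misplaced reads, and no list of such regions was applied. Next came chromosome 3, 194406663 to 194410297, with 3065 ± 554 and 3254 ± 497 covered bases (SD, n = 3 each). The overlap of covered bases between 2 lists, as a Jaccard index, averaged 0.673 within normoxia (range 0.581 to 0.784) and 0.764 within hypoxia (0.726 to 0.834). Between the groups it averaged 0.715 (0.573 to 0.799). Normoxia replicate 1 covered the fewest bases (11.1 Mb), which limits its index with longer lists. Normoxia replicates 2 and 3 shared 0.784, and their values with the hypoxia lists ran from 0.709 to 0.799.

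More regions were called only in hypoxia than only in normoxia. All 3 hypoxia libraries and 0 normoxia libraries had a call in 357 regions, and the reverse held for 19. The hypoxia-only region with the longest call in its weakest library lay at chromosome 12, 120685160 to 120686765, with 1202 ± 472 covered bases (SD, n = 3). A region at chromosome 2, 219263501 to 219264362, had 781 ± 105 covered bases, and 1 at chromosome 3, 30334003 to 30334851, had 754 ± 108 (SD, n = 3 each). The last 2 of the 5 named were chromosome 3, 129374711 to 129375540, with 680.0 ± 132.1 covered bases, and chromosome 9, 131675002 to 131675792, with 567 ± 129 (SD, n = 3 each). The region at chromosome 2 lay 285 bases from a region called in all 6 libraries. Among the 19 normoxia-only regions, the named ones began at 34203748 and 39633102 on chromosome 20, 150036354 on chromosome 5, 93473272 on chromosome 11 and 82648457 on chromosome 15. Their mean covered lengths were 323 ± 39.2, 623 ± 334, 299 ± 40.2, 213.0 ± 28.8 and 230.3 ± 72.3 bases in that order (SD, n = 3 each).

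Group-only regions were shorter and more weakly called than regions called in all 6 libraries. The hypoxia-only regions had a median length of 268 bases and the normoxia-only regions 262. Their best peaks sat at a median percentile of −log10 q between 12.9 and 19.6 in the hypoxia lists and between 10.9 and 16.4 in the normoxia lists. Regions called in all 6 libraries sat between 60.1 and 72.6. Any region missed by some lists is likely to lie near the calling threshold. Other partly called regions were not compared, so this trait is not shown to be particular to group-only regions. Of the hypoxia-only regions, 136 (38.1%) lay within 1 kb of a region called in all 6, against 32.1% of those shared regions themselves. Hypoxia-only regions made up 6.79 to 13.45 per 1000 consensus regions of a chromosome, and no difference from the rest passed the test (Fisher's exact test, 23 chromosomes, all adjusted p = 1).

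The imbalance shrank or turned at equal list length. With the strongest 21887 peaks of every list, 56 regions were called only in hypoxia and 100 only in normoxia, and 16 and 2 of the regions above were kept. Without the 2 weakest libraries, a choice made after the data were seen, equal lists of 26478 peaks gave 465 and 415. Of the named hypoxia-only regions, those on chromosomes 12 and 9 had no call left in any library at equal list length of 21887 peaks. With intervals within 500 bases merged, the region on chromosome 2 joined calls of all 3 normoxia libraries and that on chromosome 12 a call of 1. Of the 5 named normoxia-only regions, the 1 on chromosome 5 kept its status at equal list length, and all 5 lost it with intervals merged, each joined by a call of at least 1 hypoxia library. At a −log10 q of at least 5 the region on chromosome 5 kept calls in 2 of the 3 normoxia libraries. The region starting at 129374711 on chromosome 3 stayed hypoxia-only in all 14 alternatives. Those that only left out libraries or chromosome X could hardly have ended that status. Leaving out a library asks fewer libraries to agree, so the counts of group-only regions could hardly fall. Leaving out normoxia replicate 2, normoxia replicate 3 or hypoxia replicate 2 gave 960, 567 and 1442 hypoxia-only regions. Normoxia-only regions numbered 131, 34, 33, 31 and 41 without normoxia replicates 1, 2 and 3 and hypoxia replicates 2 and 3.

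**Figure D2:**
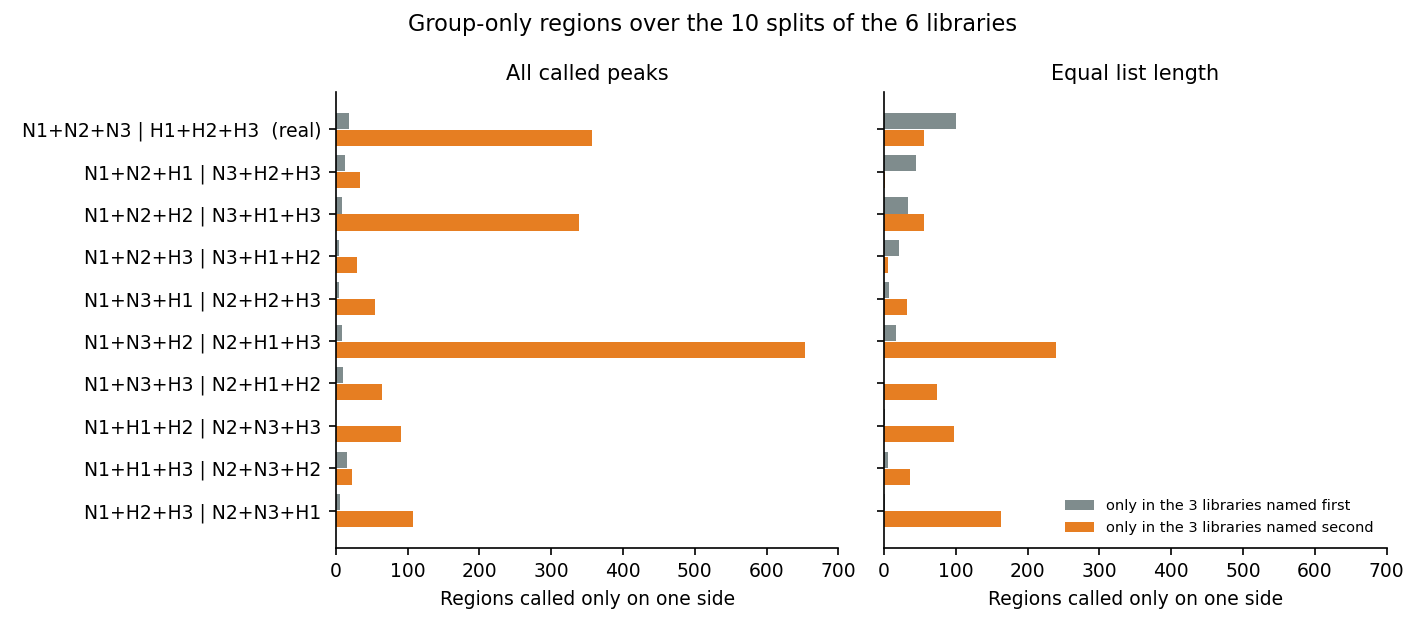
Regions called only on one side, in number, for each of the 10 ways to split the 6 libraries (N, normoxia; H, hypoxia; the number is the replicate) into 3 and 3, with all called peaks (left) and with 21887 peaks per list (right). The real split gives 19 and 357 regions on the left and 100 and 56 on the right; another split reaches 654 on the left and 240 on the right.

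H3K4me3 was broader in hypoxia at 2 of the 16724 regions called in all 6 libraries, and 0 regions were narrower (limma, Benjamini-Hochberg adjustment). At chromosome 14, 34418486 to 34420310, covered bases rose from 331 ± 117 in normoxia to 1553 ± 233 in hypoxia (SD, n = 3 each). The log2 difference was 2.19 (SE 0.164, limma adjusted p = 0.0185). At chromosome 20, 48183104 to 48184861, they rose from 571 ± 133 to 1436 ± 260 (SD, n = 3 each), a log2 difference of 1.24 (SE 0.110, limma adjusted p = 0.0322). Both regions grew on the side of lower coordinates. On chromosome 14 the first covered base moved from between 34419883 and 34420084 in normoxia to between 34418486 and 34418817 in hypoxia, while the last covered base fell between 34420255 and 34420310 in all 6 libraries. On chromosome 20 it moved from between 48184195 and 48184288 to between 48183104 and 48183307. In hypoxia replicate 2 the first covered base belonged to a separate interval of 141 bases at both regions. The longest interval of that library began at 34419269 on chromosome 14 and at 48183793 on chromosome 20. At both regions each hypoxia library covered more bases than every normoxia library.

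**Figure D3:**
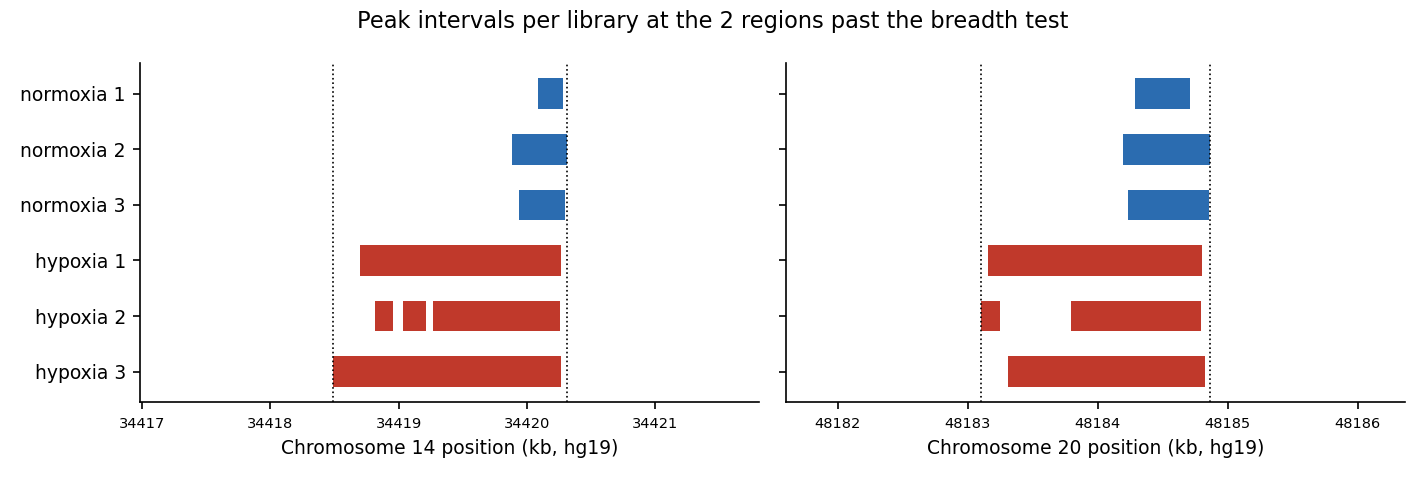
Peak intervals of each library (bars; blue, normoxia; red, hypoxia) along chromosomes 14 and 20 in kb of hg19, with dotted lines at the ends of the consensus region. Hypoxia intervals reach further to the left, and hypoxia replicate 2 has 3 separate intervals on chromosome 14 and 2 on chromosome 20.

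The next regions did not pass the test. At chromosome 12, 12938586 to 12940504, covered bases were 863 ± 207 in normoxia and 1701 ± 238 in hypoxia (SD, n = 3 each; log2 difference 0.90, limma adjusted p = 0.0515). It passed in 4 of 19 alternatives (limma adjusted p 0.0259 to 1), equal list length among them (0.0332), where the region on chromosome 20 did not (0.0677). At chromosome 4, 186317798 to 186318687, they were 304 ± 115 and 753 ± 58.6, and at chromosome 11, 89223198 to 89224830, they were 904 ± 198 and 1453 ± 226 (SD, n = 3 each; limma adjusted p = 0.26 for both). In the other direction the smallest p belonged to chromosome 16, 2203323 to 2205350, with 1497 ± 306 and 783 ± 164 covered bases in normoxia and hypoxia (SD, n = 3 each; limma adjusted p = 0.26). Its log2 difference of -1.04 became -0.13 without normoxia replicate 1 and -0.27 without normoxia replicate 2, where regions were merged anew. With no library left out it was -0.24 at a −log10 q of at least 5 and -0.23 at 10. At equal list length it was -1.24 and passed (limma adjusted p = 0.00792). Spread was small at chromosome 4, 1723213 to 1724076, with 844 ± 16.8 and 412 ± 18.0 covered bases (SD, n = 3 each; limma adjusted p = 0.26), and its log2 difference of -1.14 became -0.47 with intervals merged. The other 3 named narrower regions began at 122931740 on chromosome 11, 55351841 on chromosome 1 and 39815741 on chromosome 9, with log2 differences of -0.74, -0.69 and -1.21 and an adjusted p of 0.26 each.

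**Figure D4:**
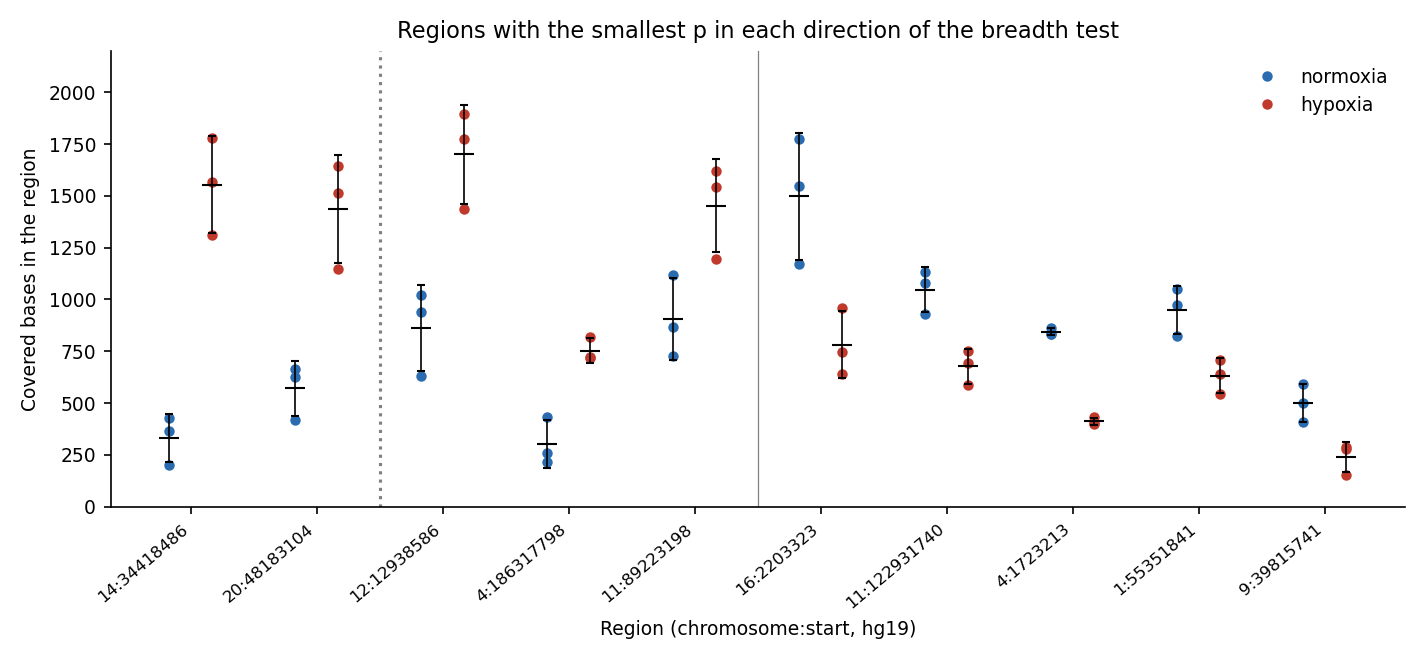
Covered bases per library (points), with mean and SD of 3 libraries (black), at the 5 regions with the smallest p in each direction of the breadth test, named by chromosome and hg19 start. The 2 regions left of the dotted line passed; the solid line separates broader from narrower regions, and groups do not overlap at any of the 10.

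Centring each library on its median holds the shift across all tested regions near 0, so the size of that shift is no finding. At an unadjusted p under 0.05, 527 regions were broader and 367 narrower in hypoxia, 894 in all, or 5.35%. The other 9 splits of the libraries gave 232 to 1728 such regions. Without centring the counts were 234 broader and 56 narrower, with a median log2 difference of 0.0845. That lean cannot be told apart from a difference in depth or yield. Groups did not overlap at 12.63% of regions, where chance gives 10%, with hypoxia above at 1025 and below at 1088. The 2 calls were lost at a −log10 q of at least 5, without centring and without any 1 of normoxia replicates 2 and 3 and hypoxia replicates 1, 2 and 3 (0 regions broader in each case), while their log2 differences stayed between 2.02 and 2.29 on chromosome 14 and between 1.08 and 1.34 on chromosome 20 over all alternatives that tested them. Without normoxia replicate 1, 8 regions were broader, and at equal list length 3 were broader and 3 narrower.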

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

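The equal list length, the fit without centring and the splits were set before the data were examined, but the first 2 and the splits for group-only regions were read as tests of an explanation only after the results were seen. The test of the weak libraries was chosen only after they were seen. Other contigs, which the comparisons leave out, also carried called peaks. Patch, alternate haplotype and unplaced contigs held 1129 to 1735 peaks per library, of which 328 to 534 lay on alternate haplotypes of chromosome 6.

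The mitochondrial contigs M and MT, which are 2 versions of the mitochondrial sequence, held at least 9 peaks each in every library, up to 10 on M and 11 on MT. The explanation that reads that map equally well to 2 copies were kept requires the same peaks on both. In every library 0 peaks on M had a peak on MT that started within 10 bases, which argues against it. No biological explanation was tested, and the origin of the mitochondrial signal stays open.

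More regions were called only in hypoxia than only in normoxia, 357 against 19. Longer peak lists in hypoxia are a candidate explanation: at equal list length 56 regions were called only in hypoxia and 100 only in normoxia, and without the 2 weakest libraries at equal list length 465 and 415. A weak and a strong library on each side is argued against as the whole cause, because with all called peaks the other splits that also part the weakest libraries reached at most 64 regions on 1 side. Those splits also mix long and short lists. At equal list length they reached 74, against the real 100 and 56, and with 4 equal lists another split reached 514, against 465, so a part played by weak libraries stays open. Whether the longer lists come from depth, yield or an effect of hypoxia stays open, since the depth is unknown. Of the 10 splits of the 6 libraries, 2 gave at least 357 regions on 1 side. All 10 gave at least 19, the normoxia-only count, on their larger side. That comparison decides nothing, because 19 was the smaller side of the real split. On their smaller side the other splits gave 0 to 16 regions. On the larger side the highest other split gave 654. It set normoxia replicate 2 and hypoxia replicates 1 and 3 against the rest. These were the lists with the largest covered lengths (18.3 to 18.7 Mb, against 11.1 to 15.9 Mb). With 10 splits no share under 0.05 can be had.

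At 2 regions H3K4me3 was broader in hypoxia. Fragment length differences between libraries are argued against as the whole cause by the smallest peak width of each list, a stand-in for fragment length. This width was larger in normoxia replicates 1 and 2 than in every hypoxia list, while the explanation needs longer fragments in hypoxia. In hypoxia only replicate 2 exceeded normoxia replicate 3. Subtracting the width decides nothing, because taking a similar amount from a short and a long covered length could hardly lower their log2 difference. After the subtraction the log2 differences were 2.26 (SE 0.223) and 1.25 (SE 0.147), against 2.19 (SE 0.164) and 1.24 (SE 0.110) before. The calls ended there as the standard errors grew (adjusted p of 0.0948 and 0.161). A widening common to all regions is argued against as the whole cause by the centring itself, which had already removed it from both differences. The fit without centring gives only its size. There the median log2 difference of all 16724 regions was 0.0845, and the smaller of both differences was 1.34 (SE 0.224). A widening limited to some kinds of region stays open. A response of these regions to hypoxia remains a hypothesis, found and tested on the same data. Of the 10 splits, 1 gave as many broader regions as the real 2, the real split itself, and the highest other gave 0; a real count of 0 narrower regions is reached by all 10 by definition and tests nothing. With 10 splits no share under 0.05 can be had.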

How the results depend on the processing

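Leaving out both weakest libraries, cyclic loess and fragment length subtraction were chosen after the data were seen. The cause was not tested where a setting removes no peaks or libraries. Regions called only in hypoxia numbered 56 at equal list length, 110 at a −log10 q of at least 10, 214 with intervals within 500 bases merged and 1468 without the 2 weakest libraries, against 357. Regions called only in normoxia numbered 100 at equal list length, 9 and 4 at a −log10 q of at least 5 and 10, 167 without the 2 weakest libraries and 415 when these lists also had equal length (hypoxia-only, 465), against 19. The difference between both counts, 338, turned to -44 at equal list length and was 50 when the 2 weakest libraries were also left out. Leaving out 1 library gave 364 to 1442 and 28 to 131 regions. With 1 or 2 libraries left out fewer libraries must agree, so without a change of list length these counts could hardly fall. Regions broader in hypoxia (limma) numbered 0 at a −log10 q of at least 5 or 10, without centring, with fragment length subtracted and without the 2 weakest libraries (234 to 1144 at an unadjusted p under 0.05), 1 without the trend, 1 with cyclic loess and 4 with intervals merged, against 2. Leaving out 1 library gave 0 to 8. At equal list length 3 regions were broader and 3 narrower, against 2 and 0.

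Hypoxia lists stayed longer on average with free list length, by 3666 to 6666 peaks with 1 library left out, but groups overlapped at a −log10 q of at least 10 (exact permutation p = 0.3). Covered length differed by -0.167 to 3.61 Mb when 1 library was left out. The difference in median width turned to 34.3 bases at equal list length and 24.2 bases when the 2 weakest libraries were also left out. Named breadth regions kept their direction in all 184 values. Such regions were picked by direction and p in these same data, so reversals were unlikely. Among those that did not pass, with intervals merged the broader region on chromosome 4 went from 1.27 to 0.11 and the narrower ones on chromosomes 11 and 4 from -0.74 to -0.22 and from -1.14 to -0.47, and chromosome 16 went from -1.04 to -0.13 without normoxia replicate 1. The region on chromosome 14 passed in 8 of 18 alternatives that tested it (adjusted p 0.00048 to 1) and that on chromosome 20 in 5 of 18 (0.0117 to 1).

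With the replicate block 0 regions were broader and 0 narrower, and peaks gave p = 0.25 and covered length p = 0.75 by exact sign flips (0.25 is the smallest). Deviations paired by number correlated at -0.286, -0.334 and 0.176. The 2 weakest libraries correlated best (0.356), so pairs, not assumed, stay possible. Promoter and gene list alternatives were not run. Unknown depth limits all counts.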

Other observations

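The test of neighbouring regions was chosen after the group-only regions were seen. The median log2 difference between hypoxia and normoxia, after centring each library on its median, which holds it near 0 over all regions (0.0845 without centring), was -0.015 over 3726 regions with a mean under 500 covered bases and -0.011 over 7639 regions of 500 to 1000. It was -0.026 over 5195 regions of 1000 to 2000 and 0.022 over 164 regions over 2000. In the last class 10 regions were broader and 1 narrower at an unadjusted p under 0.05 (limma), and none passed the adjusted test.

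The normoxia-only region at chromosome 20, 34203748 to 34204111, lay 471 bases from a region called in all 6 libraries. From such neighbours came the hypothesis that group-only calls go with the breadth of the nearest shared region. Of the 357 hypoxia-only regions, 175 had a region called in all 6 libraries within 10 kb, with a median log2 breadth difference of -0.05. Of 10000 draws of as many other regions called in part of the libraries, a share of 0.753 had a median as high (one-sided permutation test), so the test gave no support for the idea. For the 6 normoxia-only regions with such a neighbour the median was -0.21, lower than most draws (one-sided permutation p = 0.0123, unadjusted). This was 1 of 4 one-sided tests run on these classes, and its draws of regions hold no spread between libraries.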
